A study of Mus musculus with 4 samples.

How the data were processed

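Messenger RNA bound to tagged ribosomes was profiled on Illumina MouseRef-8 v2 expression beadchips, on which each probe is read from many beads. There were 4 arrays in 2 groups of 2. Per the labels, the RNA was immunoprecipitated through a hemagglutinin tag from punches of the mediobasal hypothalamus, extracted with a Qiagen kit, amplified with a whole-transcriptome kit and labelled with biotin. All 4 arrays shared 1 beadchip, so no slide effect separates the groups. The virus-injected arrays held positions B and D and the lineage arrays F and H, so position on the beadchip cannot be told apart from group. The labels do not say whether a replicate was 1 animal or a pool, and p-values therefore measure the spread between these samples, which may be technical.

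The deposited table of the whole series gives, per the file headers, an average intensity for each probe with its bead number, the standard error over beads and a detection p-value. GenomeStudio produced the values, per the submitters' processing notes, without a stated version. The deposited intensities showed no sign of background subtraction or scaling, since their means differed between arrays (1111 to 1192). The deposited detection p-values move in equal small steps and were taken as the share of negative control probes as bright as the probe. A further table of intensities that the authors processed was used only as an alternative. Each of its columns was a straight line of the same array's deposited intensity, with residuals of at most 0.0101. A constant of 416 to 440 had been subtracted, the same as the mean of the negative controls rebuilt from the detection p-values, and the array means had been made equal at 718. Its column medians were 134, 126, 122 and 130, and its values are linear, so its scale, centring and direction were settled by this comparison.

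Intensities were corrected and normalized with neqc of limma (version 3.58.1, R 4.3.3): normexp background correction from the detection p-values, an offset of 16, quantile normalization and log2. Of the 25697 probes, 12266 had a detection p-value under 0.05 on at least 2 of the 4 arrays and were tested. The platform annotation gave 1 gene symbol for 23978 probes, several for 0 and none for 1719; unnamed probes are not without a gene. Updating through the Entrez identifier changed 0 symbols. The probe with the highest mean stood for a gene, which gave 8360 genes, of which 2214 had over 1 probe past the filter. Some genes are not reported here.

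The lineage group was compared with the virus-injected group in 1 fit of all 4 arrays with lmFit and eBayes, without covariates, which leaves 2 residual degrees of freedom. P-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. An exact permutation of 2 against 2 arrays cannot give a two-sided p below 0.333, so single genes were judged only by the limma fit. On data simulated for this comparison with 8360 genes, of which 200 were changed, the fit called 0% of changes of 1 on the log2 scale, 83% of changes of 2 and 93% of changes of 3. False calls numbered 0, 11 and 17. In the data only 62 genes were higher and 105 lower by at least 1, and even Avp at -4.23 did not pass (limma adjusted p = 0.160). The simulated shares may therefore overstate the power here. Standard errors are those of the moderated fit, and SD is over the 2 arrays of a group.

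A set of 28 gene lists was fixed before the data were examined. The 23 with at least 3 measured genes were tested with camera (preset correlation 0.01), adjusted over these lists. Beside it stand camera with an estimated correlation, fry, and for single members a Benjamini-Hochberg adjustment over the list alone. The fry p-values were not adjusted over the lists. On data simulated for this comparison, camera called 100 of 100 lists of 10 genes shifted by 0.6 and 0 of 100 unshifted lists. The simulated genes varied independently, whereas the correlation estimated for the called lists ranged from -0.128 (neighbouring nuclei) to 0.397 (kisspeptin). The simulation therefore does not show how the preset performs on lists of correlated genes. In calls with the estimated correlation the test has only the residual degrees of freedom of the arrays, and 0 of the 9 called lists passed. Lists for glutamate transmission, acetylcholine, oligodendrocyte precursors, the anterior pituitary and the ribosome tag gene had too few measured genes.

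The genes named were also set by a rule fixed before the data were examined: every measured member of the POMC, NPY and kisspeptin neuron lists; in each direction the 10 genes of largest change past the threshold, filled up by smallest p where fewer passed, without overlap between groups and detected on both arrays of the higher group, leaving out provisional symbols; the 4 members of smallest p of each other list called or named in the text; and Pomc, Rpl22 and sex-linked genes. As 0 genes passed, all 20 genes of that part entered by smallest p. Where a group's 2 arrays both lay at background (detection p-value of 0.05 or more), a fold is given as "at least", computed against the higher of the lowest detected signal and the probe's own signal on each array.

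Alternatives were no background correction, median scaling, cyclic loess, no filter, a stricter filter (detection p-value under 0.01 on both arrays of a group), the authors' processed intensities with the same offset, the replicate number as a block, an eBayes trend, an unmoderated linear model, other thresholds, averaged probes, and leaving out each array. No reference genome was used, so no coordinates are given. The number of arrays limits the precision of every value.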

Results

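The arrays recorded ribosome-bound transcripts from the mediobasal hypothalamus of Pomc-Cre mice under 2 ways of tagging ribosomes. In the lineage group (n = 2 arrays), Pomc-Cre mice had been crossed to RiboTag mice, in which Cre switches on a hemagglutinin-tagged ribosomal protein RPL22 for good, so that every descendant of a Cre-expressing cell carries the tag. In the virus-injected group (n = 2 arrays), Pomc-Cre mice had received a Cre-dependent adeno-associated virus carrying the tag, which the labels equate with adult POMC neurons. The labels do not say whether the 2 arrays of a group came from separate animals. The comparison addresses which hypothalamic neurons come from precursors that once expressed Pomc but are not POMC neurons in the adult. Between 10982 and 12306 probes per array were detected, each read from a median of 38 to 39 beads. Log2 intensities correlated at r = 0.968 within the virus-injected group, 0.964 within the lineage group and 0.949 to 0.960 across the groups, over genes, which are not independent replicates.

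The lineage group had higher signals for Npy, the orexigenic neuropeptide Y, and for Tac2 and Tacr3, which encode neurokinin B and its receptor, whereas the virus-injected group had higher signals for Avp (vasopressin), Nts (neurotensin), Hdc, the histamine-synthesizing enzyme, and the forebrain homeobox gene Dlx2. Npy was at 12.07 ± 0.10 (SD, n = 2) in the lineage group and 9.47 ± 0.01 in the virus-injected group, a 6.06-fold difference. Avp lay at 8.28 ± 0.29 and 12.51 ± 0.57, and was 18.8-fold higher in the virus-injected group. No probe or gene passed an adjusted p of 0.05 in the limma fit: the count was 0 of 12266 probes and 0 of 8360 genes, with lowest adjusted p-values of 0.134 and 0.0882. At an unadjusted p under 0.05 there were 1275 probes, 594 higher and 681 lower in the lineage group, against 613 that chance gives, and 914 genes, 397 higher and 517 lower, against 418. Without adult replicate 2 the count fell to 710 of 11704 probes, against 585 that chance gives. The count of calls depended on how the spread was modelled and on the background correction, scaling and filter. A fit in which the spread follows the brightness (eBayes with a trend) called 232 probes, 100 higher and 132 lower, and values without background correction gave 50 probes, 22 higher and 28 lower. Median scaling called 5 probes, the stricter filter 2 and the authors' processed values 1, and the replicate block, cyclic loess and an unmoderated linear model 0.

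Of the 10 genes with the smallest p that were higher in the lineage group, Ttr (transthyretin) differed 3.36-fold, Calcr (the calcitonin receptor) 2.53-fold, Bcl11b (a transcription factor) 2.47-fold and Pcdh20 (a protocadherin) 2.46-fold. Tac2, Tacr3, Lama1 (a laminin chain), Kalrn and Fv1 were at background on both virus-injected arrays, and their folds were at least 2.98, 3.06, 2.91, 2.17 and 2.70. Of the 10 that were higher in the virus-injected group, Hdc differed 3.79-fold, Dkk3 (a secreted Wnt modulator) 3.03-fold and Cntnap4 (a neuronal adhesion protein) 2.42-fold. Nts differed by -1.96 (log2, SE 0.19), with a weaker difference of -0.72 on a second probe. Dlx2, Cd36, Crabp1 and Cpne9 were at background on both lineage arrays, and were at least 3.63-fold, 1.95-fold, 1.66-fold and 1.27-fold higher in the virus-injected group. Cxcl12 was 2.41-fold higher in the virus-injected group on its brightest probe, which was detected on 1 of 2 lineage arrays. A further Cxcl12 probe went the other way by 1.17 on the log2 scale. None of these 20 genes passed the adjusted threshold over all genes (adjusted p 0.0882 to 0.237). Without background correction 27 of the 112 named genes moved by over 1.5-fold, all 27 toward 0, among them Avp to -3.07, Dlx2 to -1.34, Nts to -1.03 and Ttr to 0.79.

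**Figure D1:**
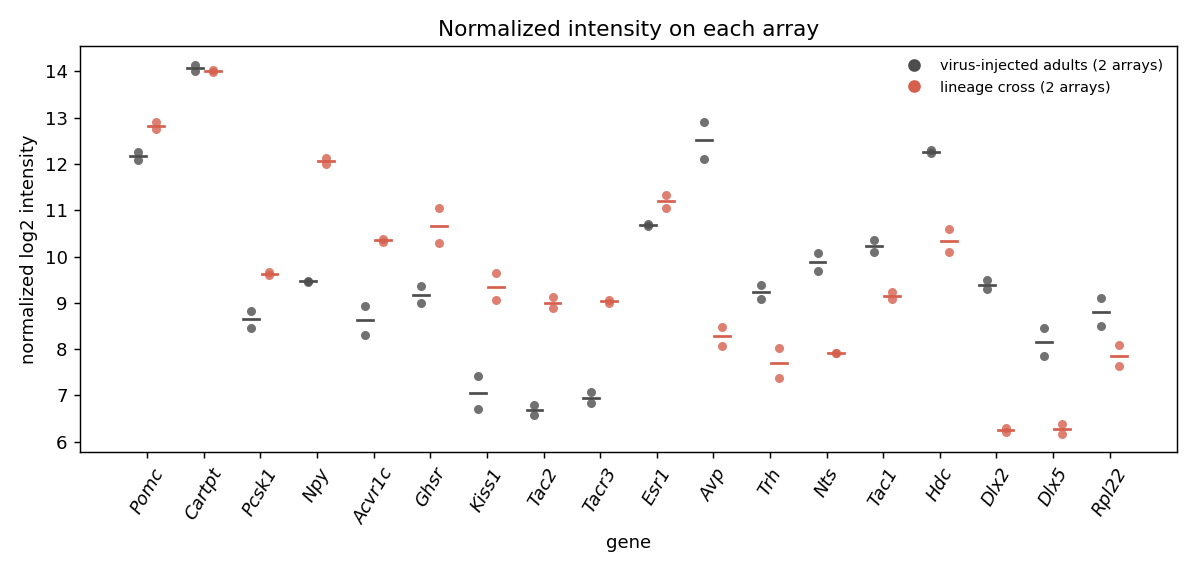
Normalized log2 intensity (vertical axis) of 18 genes (horizontal axis) on each of the 4 arrays. Points are arrays and bars are group means of 2 arrays. Npy, Kiss1, Tac2 and Tacr3 lie higher on both lineage arrays, Avp, Hdc and Dlx2 on both virus-injected arrays, and the means of Cartpt are 14.02 and 14.08.

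The POMC neuron list was called higher in the lineage group (camera, median log2 difference 0.60, adjusted p = 0.00414). Its adjusted p was 0.441 with an estimated correlation, and its unadjusted fry p was 0.0329. Pomc itself was at 12.83 ± 0.11 (SD, n = 2) in the lineage group and 12.17 ± 0.11 in the virus-injected group, a 1.57-fold difference (log2 0.65, SE 0.15, limma adjusted p = 0.349 over all genes; 7.45e-04 with a trend, the lowest over its alternatives, of which the highest was 0.756). Of the 9 measured genes of the list, 2 were higher when adjusted over the list alone, Pomc and Pcsk1 (the prohormone convertase that cleaves the POMC precursor, log2 0.98, SE 0.18), and 7 did not pass. Among those 7, the log2 difference was 0.71 for Lepr (the leptin receptor), 0.65 for Nr3c1 (the glucocorticoid receptor), 0.60 for Mc3r (a melanocortin receptor), 0.28 for Tbx3, 0.11 for Isl1 and -0.06 for both Insr and Cartpt, the peptide that many POMC neurons also make. The remaining Tbx3 probes were at 1.59 and 0.61. With 1 array left out, Lepr ranged from 0.45 to 0.97, Nr3c1 from 0.29 to 1.02, Mc3r from 0.35 to 0.85, Tbx3 from 0.094 to 0.47 and Isl1 from 0.021 to 0.20. Over all genes 0 of its members passed.

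All 7 measured genes of the NPY neuron list had a higher mean in the lineage group. Adjusted over the list alone, 4 were higher: Npy (log2 2.60, SE 0.14), Acvr1c (an activin receptor, 1.74, SE 0.25), Ghsr (the ghrelin receptor, 1.49, SE 0.31, with 1.20 on another probe) and Corin (a serine protease), which was at background on both virus-injected arrays and at least 1.60-fold higher in the lineage group. The other 3 were at 0.71 for Npy2r (0.36 to 1.06 with 1 array left out), 0.38 for Sphkap and 0.23 for Asb4. Over all genes 0 passed. The list was higher in the lineage group (camera, median 1.29, adjusted p = 1.2e-06). Its adjusted p was 0.271 with an estimated correlation, and its unadjusted fry p was 0.00423.

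Of 10 genes of kisspeptin neurons, the arcuate cells that drive gonadotropin-releasing hormone neurons, 4 were higher in the lineage group when adjusted over the list alone, Kiss1, Tac2, Tacr3 and the nuclear receptor gene Nr5a2 (log2 1.34, SE 0.31), and 6 did not pass. The list was called higher (camera, median 0.65, adjusted p = 9.1e-05). Its adjusted p was 0.441 with an estimated correlation, and its unadjusted fry p was 0.0363. Kiss1, the gene of kisspeptin, was at 9.35 ± 0.42 (SD, n = 2) against 7.06 ± 0.50, and was detected on both lineage arrays but on only 1 of 2 virus-injected arrays. Its log2 difference of 2.29 was 0.99 without background correction, and those of Tac2 and Tacr3 were 0.92 and 0.84 there. Tac2 was at least 2.98-fold higher and Tacr3 at 9.04 ± 0.05 against 6.94 ± 0.17, in both cases with the virus-injected arrays at background. Among the 6, the third KNDy peptide gene Pdyn (dynorphin) was high in both groups and differed by 0.22, Esr1 (estrogen receptor alpha) by 0.52 with 0.03 on another probe, Pgr (the progesterone receptor) by 0.21, Npr3 by 0.77 (0.26 to 1.29 with 1 array left out), Inhbb by -0.26 (-0.48 to 0.15) and Nhlh2 by -0.48. Without lineage replicate 1 the camera call ended (adjusted p = 0.0683; the alternatives ranged from 1.8e-06 to 0.441), and over all genes 0 members passed.

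Receptors for metabolic and sex hormones formed the only other list that was higher in the lineage group (camera, median 0.52, adjusted p = 1.5e-04). Its adjusted p was 0.271 with an estimated correlation, and its unadjusted fry p was 0.00188. Adjusted over the list alone, 3 of 15 genes were higher, Tacr3, Ghsr and Ghr, the growth hormone receptor (log2 0.78, SE 0.14), and 12 did not pass, among them Thrb at -0.57. Of the 15 genes, 9 belonged to the POMC, NPY or kisspeptin lists, and without these the remaining 6 gave an adjusted p of 0.380.

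Of 8 measured genes of neurons in neighbouring nuclei, 6 were lower in the lineage group when adjusted over the list alone and 2 did not pass. The list was called lower (camera, median -1.43, adjusted p = 1.3e-05). Its adjusted p was 0.271 with an estimated correlation, and its unadjusted fry p was 0.00207. The 6 were Avp (log2 -4.23, SE 0.33), Hdc (-1.92, SE 0.22), Trh, which encodes thyrotropin-releasing hormone (-1.53, SE 0.28), Ppp1r17, a gene of the dorsomedial hypothalamus (-0.88, SE 0.17), both detected on 1 of 2 lineage arrays, and, named after their values were seen, Oxt (oxytocin, -1.33) and Pmch (melanin-concentrating hormone), which was at background on both lineage arrays. Nr5a1, the marker of the ventromedial nucleus, and Foxb1 were named after their values were seen and lay at 0.22 and -0.32.

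Among 15 other hypothalamic neuropeptide genes, 7 were lower in the lineage group when adjusted over the list alone, including Avp, Nts, Trh and Tac1 (substance P, -1.07, SE 0.17) and, named after its values were seen, Ghrh (growth hormone-releasing hormone, at least 3.35-fold lower). The other 8 did not pass, and 5 of these had a higher mean in the lineage group. This list was lower (camera, median -0.54, adjusted p = 0.00246). Its adjusted p was 0.446 with an estimated correlation, and its unadjusted fry p was 0.0480. Without adult replicate 1 its adjusted p was 0.0545, and without the 4 genes shared with the neighbouring nuclei list it was 0.306.

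Of 15 hypothalamic developmental transcription factors, 3 were lower in the lineage group when adjusted over the list alone: Dlx2, Dlx5 and Dlx1, homeobox genes of GABAergic forebrain neurons, all at background on both lineage arrays and at least 3.63-fold, 1.54-fold and 1.42-fold lower. Nkx2-2 did not pass. This list was not called (camera adjusted p = 0.0966), and its median of 0.04 and its mean of -0.47 differed in sign, the test pointing down. Its unadjusted fry p was 0.00319, so camera and fry differed here. Neither transmitter list was called. In the GABA list (4 genes, adjusted p = 0.585), Slc32a1 (the vesicular GABA transporter) was at -0.46 (-0.65 to -0.28 with 1 array left out), Gad2 at 0.19 and Gad1 at -0.0043, and no gene passed over the list alone. In the dopamine list (6 genes, adjusted p = 0.985), Th (tyrosine hydroxylase) was at -1.57 (SE 0.51, detected on 1 of 2 lineage arrays, -2.20 to -0.92 with 1 array left out) and Gch1 at 0.72, with 0.22 on another probe, neither past the list-alone threshold. The 16 pan-neuronal genes gave a camera adjusted p of 0.414, with a median of 0.10 and an unadjusted fry p of 0.0170.

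**Figure D2:**
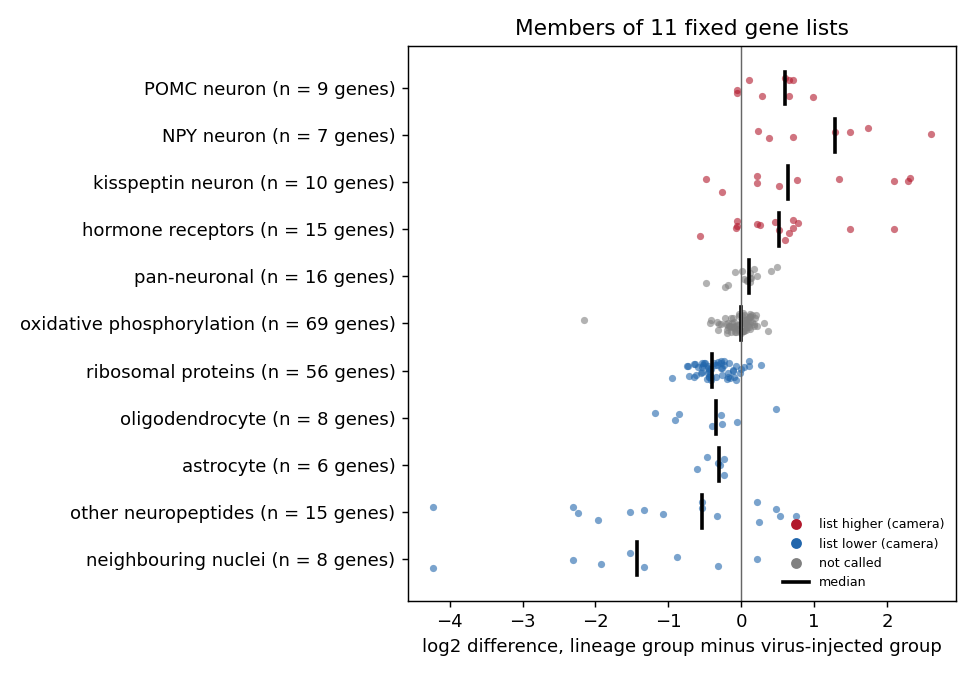
Log2 difference of each measured gene, lineage minus virus-injected group (horizontal axis), for 11 fixed lists (vertical axis). Points are genes, black bars are list medians, and colours mark the camera call. The NPY list has its median at 1.29 and the neighbouring nuclei list at -1.43, while oxidative phosphorylation has its median at 0.0027.

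The astrocyte and oligodendrocyte lists were called lower in the lineage group by camera, with adjusted p = 0.441 and 0.489 with an estimated correlation. Their unadjusted fry p-values were 0.0725 and 0.0790, so fry did not pass for either list. All 6 measured astrocyte genes had a lower mean, with none past the list-alone threshold; Gja1 (connexin 43) was at -0.61 and Ntsr2 at -0.47 (list: camera median -0.30, adjusted p = 0.00559). Of 8 oligodendrocyte genes, 1 was lower over the list alone, Mbp (myelin basic protein, -1.18, SE 0.15, with -0.10 and -0.49 on other probes), and without adult replicate 1 or 2 the Mbp difference was -0.12 or -0.075, another Mbp probe then being the brightest. Opalin, detected on 1 of 2 lineage arrays, lay at -0.91 (list: median -0.34, adjusted p = 0.0165). The astrocyte call ended without adult replicate 1 (adjusted p = 0.130) or lineage replicate 1 (0.0615), and the oligodendrocyte call without adult replicate 1 (0.201), adult replicate 2 (0.131), lineage replicate 2 (0.131) or Mbp (0.114, a setting chosen after the data were seen). The lists for microglia (3 genes, adjusted p = 0.178), endothelial and mural cells (6 genes, 0.575), tanycytes and ependyma (4 genes, 0.0560) and blood (3 genes, 0.473) were not called. In them the mural cell gene Rgs5 was lower over the list alone (-1.47, SE 0.26) and Ttr was higher.

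The list of cytosolic ribosomal proteins was called lower in the lineage group, with 51 of 56 genes lower by their means. It had a median of -0.40 (camera adjusted p = 7.3e-12). Its adjusted p was 0.271 with an estimated correlation, and its unadjusted fry p was 0.00204. No member passed alone (adjusted over the list alone, 0 of 56); Rps27 was at -0.74, Rpl39 at -0.73, Rpl37a at -0.72 and Rps15 at -0.64. The 69 oxidative phosphorylation genes, a further abundant housekeeping group, had a median of 0.0027 (adjusted p = 0.585). Rpl22, the gene whose product carries the tag, was 1.93-fold higher in the virus-injected group (8.80 ± 0.43 against 7.86 ± 0.32, SD, n = 2; limma adjusted p = 0.401), but the log2 difference of -0.95 ranged from -1.26 to -0.41 over its alternatives, and whether its probe also reads the tagged copy is not known here.

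No list of antiviral or injury responses was called. Of 7 interferon response genes, 3 were lower in the lineage group over the list alone, Ifit3 (-0.56, SE 0.14), Oasl2 (-1.29, SE 0.35, detected on 1 of 2 lineage arrays) and Ifitm3, which was at background on both lineage arrays and at least 1.24-fold lower, while Irf9 was at 1.07, with 0.46 to 1.70 when 1 array was left out. The list had an adjusted p of 0.707, with a median of 0.23 and a mean of 0.0074 against a test that pointed down. The antigen presentation list (8 genes, adjusted p = 0.956, median -0.16, mean 0.03) and the list for reactive glia and injury (8 genes, adjusted p = 0.0917) were not called by camera. The injury list had an unadjusted fry p of 0.0381. Serpina3n, an acute-phase gene of the injury list, was higher in the lineage group over the list alone (0.82, SE 0.17). Among 9 immediate early genes, Jun (0.93, SE 0.16) and Fosb (at least 2.97-fold) were higher over the list alone, and the list had an adjusted p of 0.0986. It was called higher with a trend (0.0328), without background correction (0.0437), without a filter (0.00526) and without lineage replicate 2 (0.0476), and its alternatives ranged up to 0.931. The sex-linked transcripts Xist, Uty and Eif2s3y were each detected on both arrays of each group, so each array may hold RNA from animals of both sexes. Xist, expressed from the inactive X chromosome, was at 11.33 ± 0.03 in the virus-injected group and 10.69 ± 0.35 in the lineage group, and the Y-linked genes Uty and Eif2s3y differed by -0.03 and 0.13 (list adjusted p = 0.558).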

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

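The settings that drop the member of largest change or the members shared with a related list were chosen after the data were seen. The limma fit called 0 probes and 0 genes, and so did cyclic loess, no filter, an unmoderated linear model and leaving out each array. A trend gave 232 probes and 203 genes, no background correction 50 and 56, median scaling 5 and 4, the stricter filter 2 and 2, the authors' processed values 1 and 1, and an adjusted p under 0.1 gave 0 probes and 2 genes. Pomc kept its log2 difference of 0.65 with a trend and passed there (adjusted p = 7.45e-04). With an estimated correlation the adjusted p was 0.271 for the NPY neuron list, 0.441 for the POMC neuron list and 0.441 for the kisspeptin list. Leaving out 1 array at a time, which leaves a lone sample assumed to vary like the other group, the kisspeptin list ranged from 3.33e-06 to 0.0683, the highest without lineage replicate 1. Of the other lists, 1 was called higher and 5 lower; these counts were 0 and 0 with an estimated correlation. The count called higher was 0 without shared members, 2 with a trend, median scaling, no background correction or no filter, and 1 to 3 without 1 array; the count called lower was 2 to 6 without 1 array. The unmoderated model gives no list test. Except where a setting's construction shows it, as with shared members, the cause was not tested. Over all settings 284 list values kept direction and side of the threshold, 19 lost the call, 12 gained it and 23 changed direction; of the named genes 1419 values kept both, 75 gained the call and 18 changed sign. Calls gained were the immediate early genes (0.0328 with a trend, 0.0437 without background correction, 0.00526 without a filter, 0.0476 without lineage replicate 2), tanycytes and ependyma (0.0386 with median scaling, 0.0257 with the block, 0.0191 without adult replicate 1, 0.0366 without lineage replicate 2), the developmental transcription factors (0.0386 with median scaling), and, without adult replicate 2, microglia (0.0120), endothelial and mural cells (0.0402) and reactive glia (0.0389). The oligodendrocyte call ended without Mbp (0.114). Of the 112 named genes, 27 moved by over 1.5-fold without background correction, all toward 0, 8 with the authors' processed values, 0 of them toward 0, and 3 with the probes of a gene averaged. Low signal over background limits genes at background in a group.

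With the replicate block, 0 probes and 0 genes passed and 2 other lists were called higher, the tanycyte and ependymal list being added (adjusted p = 0.0257). Same-numbered arrays did not deviate together (correlation -0.024), and the labels tie the numbers to no shared animal or day.

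Some values that had not passed changed sign, the cause of which was not tested. For lists the adjusted p of the test in the other direction is given, and for genes the log2 difference. With a trend it was 0.927 for the dopamine synthesis and transport list and 0.979 for the interferon response list. Without the member of largest change it was 0.88 for the endothelial and mural list, 0.958 for the GABA transmission list and 0.88 for the interferon response list. Without background correction it was 0.959 for the antigen presentation list and 0.959 for the dopamine synthesis and transport list. Without a filter it was 0.571 for the dopamine synthesis and transport list, 0.977 for the interferon response list, 0.702 for the microglia list and 0.951 for the sex-linked list. With the probes of a gene averaged it was 0.12 for Abat and 0.862 for the dopamine synthesis and transport list. With the replicate block it was 0.959 for the dopamine synthesis and transport list. With the stricter filter it was 0.881 for the antigen presentation list. Without 1 array, genes that changed sign ranged as log2 differences over Cartpt -0.12 to 0.0012, Ddc -0.043 to 0.43, Eif2s3y -0.32 to 0.58, Frzb -0.51 to 0.31, Gad1 -0.21 to 0.20, Gad2 -0.0046 to 0.38, Hbb-bt -0.031 to 0.30, Inhbb -0.48 to 0.15, Insr -0.26 to 0.13, Laptm5 -1.08 to 0.027, Ly6c1 -0.50 to 0.16, Slco1c1 -1.44 to 0.026, Sox2 -0.13 to 0.33 and Uty -0.23 to 0.17. Lists that changed direction ranged in adjusted p over the antigen presentation list 0.64 to 0.931, the dopamine synthesis and transport list 0.686 to 0.989, the hypothalamic developmental transcription factors list 0.111 to 0.678, the immediate early genes list 0.0476 to 0.931, the interferon response list 0.0713 to 0.917 and the sex-linked list 0.279 to 0.989.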

Other observations

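The tests on unbound RNA, virus spread, dilution, the sexes and short transcripts were chosen after the result was seen. The 5 genes named next lie outside the fixed lists and were chosen after their values were seen; none passed the limma threshold over all genes. The orphan nuclear receptor genes Nr2f1 and Nr2f2 were 3.10-fold and 3.69-fold higher in the virus-injected group, with -1.47 (log2) on another Nr2f2 probe. Reln (reelin) was 7.62-fold higher there, with an SD of 1.27 between the lineage arrays, of which 1 detected it, and the transcription factor gene Nfix was 2.69-fold higher. Lmo3, a LIM-domain gene, was 1.89-fold higher in the lineage group, with 1.10 (log2) on another probe.

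Npy and Kiss1 were higher in the lineage group by 2.60 and 2.29 on the log2 scale, Kiss1 being detected on 1 of 2 virus-injected arrays, and Tac2 and Tacr3 by at least 1.57 and 1.61, while Cartpt was at -0.06. Dilution of arcuate transcripts by other RNA in the virus-injected group would act on Pomc too. The upper 95% bound for Pomc was 1.06, under the lower 95% bounds of 2.22 for Npy and 1.41 for Kiss1. It was also under the "at least" values for Tac2 and Tacr3, for which no sampling error was computed. The fitted differences of Tac2 and Tacr3 had lower 95% bounds of 1.85 and 1.67, but rest on virus-injected arrays at background. The share of POMC neurons among tagged cells can differ by design, though, which would move Pomc apart from dilution. The comparison therefore cannot exclude dilution, and shows only that Pomc differed by less than these genes. Without background correction, which leaves the background in dim values, the upper bound for Pomc was 0.88. Only the lower 95% bound of Npy (1.79) lay above it, against 0.66 for Tac2, 0.59 for Tacr3 and 0.65 for Kiss1. The normalization sets the size of the differences, whose lowest fitted value under 4 other normalizations was 0.84, but not their direction. A different mix of sexes cannot be told apart, because Xist differed by -0.64 while the Y-linked genes Uty and Eif2s3y were at -0.03 (SE 0.20) and 0.13 (SE 0.33); descent from Pomc-expressing precursors, which the design names, stays open, untested.

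The neighbouring nuclei list was called lower in the lineage group, though not with an estimated correlation (adjusted p = 0.271), and 2 of its 8 genes did not pass. More unbound RNA from all cells of the punch would raise glial markers too. The mean log2 difference of 8 neighbouring nuclei genes minus that of 17 glial genes was -1.13 (exact two-sided permutation p = 0.00191 over genes, which are not independent replicates). The glial mean was -0.41, also lower in the lineage group. How far unbound RNA raises each gene depends on its level in the whole punch, which was not measured. The comparison therefore cannot exclude unbound RNA. Virus that tagged cells outside the arcuate nucleus, which would need Cre in those cells, and punches that held more of them cannot be told apart. Both could raise Avp (-4.23), and unfractionated punches were not analysed here. Nr5a1, the marker of the ventromedial nucleus, was not higher in the virus-injected group.

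The ribosomal protein list was called lower in the lineage group, though not with an estimated correlation (adjusted p = 0.271), and 0 of its 56 genes passed over the list alone. The tables argue against the normalization, since the median nearest to 0 under 4 other normalizations was -0.31, and against a trend with brightness, since 0% of 10000 lists matched on mean intensity had a median as low. Loss of short transcripts would lower oxidative phosphorylation genes as far as they are short. Their median was 0.0027, and their mean of -0.05 lay above the ribosomal mean of -0.35. The permutation p of this difference in means was 1e-04, the smallest that these resamples can give. It was taken over genes, which are not independent replicates. Transcript lengths were not compared, so loss of short transcripts stays open. The cell types tagged, which differ by design, stay open and were not tested.

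The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 1275 probes with an unadjusted p under 0.05 and the highest of the others 519, so that 1 of 3 splits gave as many.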
